A study of Mus musculus with 24 samples.

How the data were processed

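The series measured messenger RNA by bulk RNA sequencing in whole ovary, uterus, pituitary and hypothalamus of C57BL6 females at 2.5 days post coitus, from wild-type mice and from mice labelled as Kdm4a knockout. Kdm4a encodes a histone demethylase that acts on methylated lysines of histone H3. Per the labels' protocols, virgin females 8 to 10 weeks old were mated at 2 females per male, presence of embryos was checked by flushing the oviduct, and tissues were cleaned of fat and frozen. The labels call the 3 libraries of each group biological replicates and give RNA integrity numbers of at least 8. Libraries were made from 0.5 µg of total RNA with poly-A selection, an unstranded TruSeq kit and 13 cycles of PCR, per the labels' protocols. Without strand, reads from overlapping antisense genes cannot be told apart.

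The authors deposited raw read counts per gene symbol for each library. The submitters' processing notes name FastQC, Trimmomatic, STAR, HTSeq, DESeq2 and the mm10 build, while their versions, settings and annotation are not given in the sources used here. The authors also deposited a comparison of genotypes per tissue, made with DESeq2 per the file headers. Per the file headers, its signal column is the mean over both genotypes of counts that the authors divided by size factors with DESeq2. It also holds the log2 fold change of knockout against wild type with its standard error, and the p-value with its adjusted value, as deposited by the authors. Mean normalised counts recomputed here from the deposited counts lay within 1% of the authors' means for 100% of genes with a mean of at least 10, in all 4 tissues.

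The count tables held 24222 entries. Of these, 27 carried a spreadsheet date where a gene symbol belonged, and they were left out of library sizes and tests. They took 0.122% to 0.392% of the counts of a library. The remaining 24195 symbols summed to 13201596 to 23865382 counts per library. At that depth 1 count is worth 0.0419 to 0.0757 CPM, the unit of counts scaled to a common library total, and errors given for single libraries cover counting only, since reads were not marked by molecular identifiers. Within groups, the 24 pairs of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 10.5 or more over genes with at least 20 counts in a pair. Gene positions, transcript length and GC content came from the GENCODE M21 and RefSeq annotation of the same mouse build.

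Genotypes were compared within each tissue, 3 libraries against 3, with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, robust fitting) and Benjamini-Hochberg adjustment at FDR 0.05. All tests were two-sided unless stated. Fold changes are log2 of KO-labelled over wild type, with an SE that matches the F statistic. CPM values are scaled by TMM and given as mean ± SD of 3 libraries. The 46 gene lists were fixed before the data were examined, as were the main tests and the rule for named genes. Lists with at least 5 tested members were tested with camera from limma 3.58.1 at a preset correlation of 0.01 between genes. The difference of the genotype effect between tissues was tested over all 24 libraries as the tissue by genotype interaction with 3 degrees of freedom. Overlaps of calls between tissues were tested with a one-sided exact hypergeometric test.

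The rule for named genes took Kdm4a in every library and the genes beside it. It then took up to 8 genes per direction with the largest fold changes among those past FDR 0.05, with non-overlapping groups and a mean of at least 1 CPM, leaving out predicted and Rik symbols. It further took the 2 members with the smallest p of each list called in a tissue or made for it. Where fewer than 5 genes passed, it took the 5 genes with the smallest p. Not every gene so taken is printed.

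Alternatives were RLE scaling, no filter, a filter of at least 1 CPM in 3 libraries (12 of 24 for the interaction), DESeq2 1.42.0, limma-voom, the label number as a block, 1 fit over 24 libraries, an estimated correlation, fry, and leaving out each library. Added after seeing the data were fits with each library's trends over GC content and transcript length removed, the ovary without a pair of libraries, and the pituitary without Prl and Gh.

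The tests were tried on simulated counts with 200 changed genes per tissue, drawn from the real means, library sizes and spread. For 4-fold changes edgeR recovered 74.2% in the ovary (14272 genes), 93.9% in the uterus (14777 genes), 95.5% in the pituitary (14044 genes) and 90.9% in the hypothalamus (14646 genes). For 2-fold changes it recovered 4.48%, 55.2%, 61.2% and 17.9% in the same order. For 1.5-fold changes it recovered 0%, 7.46%, 10.4% and 0%. False calls numbered 4 of 56, 5 of 109, 12 of 123 and 5 of 77, and a limit of 15% of calls was set for the test. The share of false calls was thus above the nominal 5% in the ovary, the pituitary and the hypothalamus. DESeq2 made 37, 25, 21 and 27 false calls on the same data. The interaction test over 16719 genes made 258 calls, of which 32 were false, also above 5%. A simulated list of 20 raised genes was called in each tissue, also with an estimated correlation. Simulated genes were drawn independently of each other. In the real data the estimated correlation reached 0.568 for uterine S phase genes and 0.975 for ovarian ribosomal genes. The simulation therefore does not show how either list test performs on such correlated lists. Its recovery rates hold for 200 changed genes of at least 1 CPM with no library that stands apart.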

Results

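The data set held 24 libraries in 8 groups, with 3 wild-type and 3 KO-labelled libraries in each of ovary, uterus, pituitary and hypothalamus. Total counts ranged from 13201596 to 23865382 per library. The design asked which genes differ between genotypes in the tissues of the reproductive axis on the third day after mating.

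Kdm4a itself (chromosome 4, 118136957 to 118180090, mm10) was counted in every library, and its groups separated in the uterus only. There it measured 113, 111 and 98.9 CPM in wild type and 72.7, 74.3 and 80.8 CPM in KO-labelled libraries, a log2 fold change of -0.50 (SE 0.12, edgeR adjusted p = 0.122). In the ovary it measured 85.1, 87.0 and 91.4 CPM in wild type and 95.5, 41.2 and 73.5 CPM in KO-labelled libraries. In the pituitary the values were 36.4, 38.5 and 32.5 CPM against 43.4, 30.1 and 33.0 CPM. In the hypothalamus they were 33.6, 46.1 and 29.4 CPM in wild type and 33.2, 67.2 and 39.1 CPM in KO-labelled libraries, with a log2 fold change of 0.35 (SE 0.31, adjusted p = 0.664). Kdm4a passed FDR 0.05 in none of the 4 tissues by edgeR, and the authors' deposited table gave an adjusted p of 0.0181 in the uterus. The labels do not state the allele, and counts summed over a gene do not show a deletion of part of it. The knockout libraries are therefore called KO-labelled throughout, since the target's counts do not separate the genotypes in 3 of the tissues. The genes on either side, St3gal3 and Ptprf, passed in none of the tissues, with log2 fold changes between -0.46 and 0.54.

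**Figure D1:**
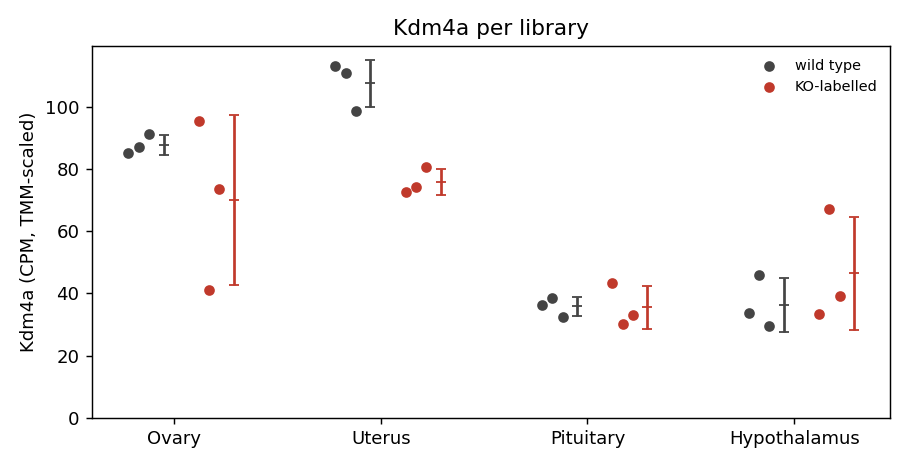
Kdm4a in each library (points) in TMM-scaled CPM, with the group mean and SD of 3 libraries beside them. In the uterus the KO-labelled libraries lie at 72.7 to 80.8 CPM, below the wild-type libraries at 98.9 to 113 CPM, and in the other tissues the groups overlap.

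In the uterus, 52 of 14910 genes passed FDR 0.05, 20 higher and 32 lower in KO-labelled libraries, and all 52 had groups that did not overlap. Over all genes tested 19.5% had such groups, where chance gives 10%. Sprr2b, a small proline-rich protein gene of surface epithelia, rose by 5.14 on the log2 scale (SE 0.81). It had 2, 3 and 5 counts in wild-type and 245, 116 and 34 in KO-labelled libraries, so the size of its change rests on few counts. Sprr2g, of the same family and annotated as a transcribed pseudogene, measured 16.0 ± 10.6 CPM (SD, n = 3) in wild type and 79.1 ± 4.27 in KO-labelled libraries. Reads shared with other family members were not tested for. Klk10, a secreted serine protease, rose from 1.30 ± 0.390 to 15.3 ± 6.78 CPM. Tnc, a matrix glycoprotein, rose from 28.5 ± 6.16 to 144 ± 61.9 CPM, and the chloride channel Cftr from 2.31 ± 0.199 to 11.2 ± 4.25 CPM. Retinaldehyde dehydrogenases rose as well, Aldh1a3 by 4.05 (SE 0.64) and Aldh1a1 by 2.14 (SE 0.33). Arhgap40 rose by 3.56 (SE 0.51), from 1, 6 and 5 counts in wild-type to 56, 54 and 48 in KO-labelled libraries.

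The genes that fell in the uterus included membrane transporters. Slc5a5, the sodium-iodide symporter, fell from 30.1 ± 16.9 to 3.12 ± 1.09 CPM, and Slc24a4 from 7.49 ± 3.06 to 0.356 ± 0.324 CPM. The dopamine receptor gene Drd4 fell from 8.20 ± 2.44 to 0.665 ± 0.284 CPM. Rps4l, annotated as a transcribed pseudogene, had a log2 fold change of -4.28 (SE 0.40, edgeR adjusted p = 0.00957). The log2 fold changes of Cyp2a5, Sox2ot, Grid2ip and Crp, which also passed, were -3.69, -3.64, -2.80 and -2.56. In KO-labelled libraries Cyp2a5 had 2, 8 and 4 counts and Sox2ot 1, 12 and 10, so the sizes of their changes rest on few counts.

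**Figure D2:**
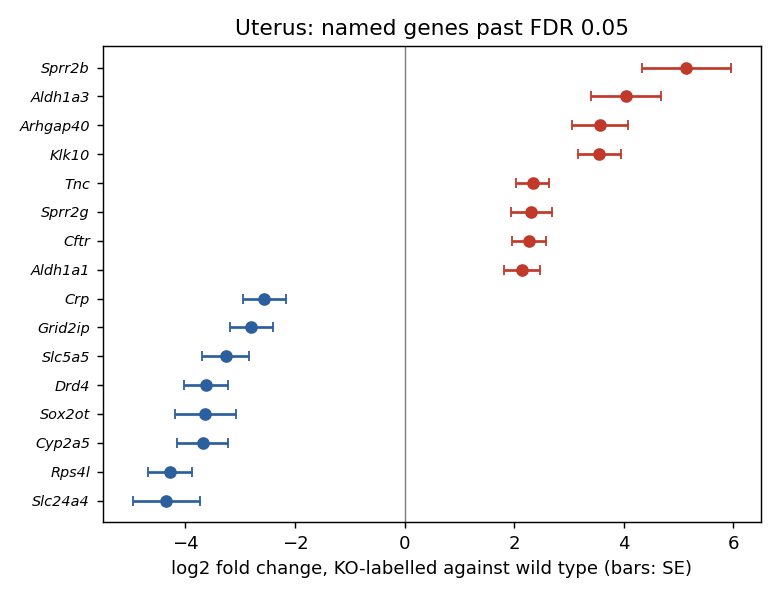
Log2 fold change in the uterus (x axis, bars are SE, 3 against 3 libraries) of the named genes past FDR 0.05. Sprr2b at 5.14 and Aldh1a3 at 4.05 are the highest of these genes, and Slc24a4 at -4.35 and Rps4l at -4.28 the lowest. Sprr2b had 2, 3 and 5 counts in wild-type libraries, and Slc24a4 had 1, 14 and 6 in KO-labelled libraries.

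The number of uterine genes past the threshold varied with the library left out. Leaving out wild-type library 1, 2 or 3 gave 5, 0 and 2 genes, and leaving out KO-labelled library 1, 2 or 3 gave 128, 148 and 171. Of 22 named genes past the threshold in the uterus, 0 passed in all 6 of these fits. Without wild-type library 1, 2 or 3 the call ended for 20, 22 and 21 of them, at adjusted p of up to 0.173, 0.277 and 0.213. Without KO-labelled library 1, 2 or 3 it ended for 3, 1 and 2, at up to 0.186, 0.0681 and 0.0555. Where a call ended, the largest shift of a log2 fold change was that of Slc5a5, from -3.27 to -2.70 without wild-type library 1. Without wild-type library 1, 2 or 3 that of Klk10 went from 3.55 to 3.32, 3.65 and 3.71, and that of Cftr from 2.27 to 2.21, 2.29 and 2.33. With no filter 108 genes passed, DESeq2 called 542, and removing each library's GC and length trends, a choice made after seeing the data, gave 99, of which 49 were among the 52.

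Of 40 lists tested in the uterus, 8 passed by camera, 6 ranked higher and 2 lower, and none of the 8 passed with an estimated correlation. KO-labelled library 1 stood apart in this tissue, at 65.6 on the first principal component (50.5% of the variance). The wild-type libraries lay at -30.5, -26.5 and -19.3 and the other KO-labelled ones at 4.57 and 6.19. Across genes the rank correlation of its deviations with length was -0.402, and those of the other 5 libraries were 0.0365 to 0.290. All 8 lists passed without it. Of 20 oestrogen-induced genes tested, 4 rose over all genes tested, and 16 passed when adjusted over the list alone, 15 of them higher (camera adjusted p = 1.7e-18). The adjusted p = 0.0615 with an estimated correlation. Among them Clca1 rose by 1.72 (SE 0.17). Of 22 S phase and mitosis genes, none passed over all genes and 19 passed adjusted over the list alone, all higher (camera adjusted p = 1.24e-20, and adjusted p = 0.328 with an estimated correlation). Plk1, a mitotic kinase, had a log2 fold change of 1.03 (SE 0.18, adjusted p = 0.0615), and Cdc20 one of 1.20 (SE 0.23, adjusted p = 0.0689). Cdc20 lies near Kdm4a, on chromosome 4 at 118432901 to 118437343, and an effect of DNA beside the targeted gene on it was not tested. Of 21 progesterone-induced genes, 2 fell over all genes and 6 passed adjusted over the list alone, all lower (camera adjusted p = 7.3e-07, and adjusted p = 0.328 with an estimated correlation). The genes that fell over all genes tested were Sult1d1, a sulfotransferase, at 214 ± 22.9 against 98.3 ± 20.9 CPM, and Calca, the calcitonin gene, at 8.58 ± 3.04 against 1.56 ± 0.685 CPM. With GC and length trends removed the log2 fold changes went from -1.12 to -1.22 for Sult1d1 and from -2.45 to -2.50 for Calca, at adjusted p = 0.0527 and 0.0502.

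Other uterine groups are given with the cell types they mark. All 7 neutrophil genes had positive fold changes and 3 passed adjusted over the list alone (camera adjusted p = 5.19e-06, and adjusted p = 0.328 with an estimated correlation). S100a8 measured 0.882 ± 0.561 and 4.39 ± 1.14 CPM and did not pass. Ltf, which is also in the oestrogen-induced list, had a log2 fold change of 1.38 (edgeR adjusted p = 0.0632). The neutrophil and oestrogen-induced lists thus share this gene, and the neutrophil list was not tested without it. Of 24 interferon-stimulated genes, 6 passed adjusted over the list alone, 4 higher and 2 lower, and over all genes Oas2 rose from 19.7 ± 1.70 to 40.1 ± 1.14 CPM (list camera adjusted p = 5.19e-05, and adjusted p = 0.456 with an estimated correlation). Of 15 heat shock genes 13 had positive fold changes and 3 passed adjusted over the list alone (camera adjusted p = 0.00288, and adjusted p = 0.328 with an estimated correlation). The adipose list ranked higher (camera adjusted p = 0.0439, and adjusted p = 0.514 with an estimated correlation), with 2 of 7 genes higher adjusted over the list alone and Cfd at 1.10 ± 0.288 and 8.83 ± 6.19 CPM. Genes of the corpus luteum, an ovarian structure, ranked lower in the uterus (camera adjusted p = 0.0164, and adjusted p = 0.456 with an estimated correlation), with 4 of 14 genes lower and 1 higher adjusted over the list alone and Cyp11a1 at 5.66 ± 1.85 and 0.898 ± 0.676 CPM. Both of these calls ended without wild-type library 3 (adjusted p = 0.0538) and with GC and length trends removed (0.0501). The adipose call also ended without KO-labelled library 2 (0.287) or 3 (0.0987). The epithelium, stroma, implantation and oviduct lists did not pass, at camera adjusted p of 0.0769, 0.275, 0.890 and 0.145. Camera asks whether a list as a whole moved in 1 direction, and single genes of these lists moved both ways. Adjusted over the list alone, 3 of 22 implantation genes passed higher and 3 lower. So did 1 and 2 of 12 stroma genes, 1 and 2 of 10 oviduct genes, and 2 and 0 of 15 epithelium genes. Within the stroma list Nt5e, an ectonucleotidase, fell from 26.2 ± 1.77 to 13.6 ± 0.949 CPM.

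In the pituitary, 6 of 14163 genes passed, 2 higher and 4 lower. Capn8, a calpain protease, rose from 1.97 ± 0.579 to 11.5 ± 6.23 CPM (SD, n = 3), and Plvap, a protein of fenestrated endothelium, from 56.5 ± 12.2 to 123 ± 18.5 CPM. Rps4l fell, with a log2 fold change of -3.86 (SE 0.32, edgeR adjusted p = 9.45e-05). So did Chil3, a chitinase-like protein gene, at -4.94 (SE 0.67), the chemokine gene Ccl28 at -2.19 (SE 0.32) and the sodium channel gene Scn7a at -1.34 (SE 0.20). With GC and length trends removed Plvap went from a log2 fold change of 1.13 to 0.80, at adjusted p = 0.0671. In this tissue the rank correlation of a gene's deviation with its GC content, across genes, was -0.263, -0.220 and -0.453 in wild type and 0.497, 0.178 and 0.127 in KO-labelled libraries. KO-labelled library 1 lay at 45.7 on the first principal component (32.1% of the variance) and the others at -26.9 to 7.87, and its rank correlation with length was -0.516 where theirs were -0.0452 to 0.269. Leaving out wild-type library 2 gave 1 gene, wild-type library 3 gave 10 and KO-labelled library 3 gave 2, while limma-voom called 1 and DESeq2 48. Rps4l was the 1 gene of the 6 that passed in all 6 leave-one-out fits. Without wild-type library 1, 2 or 3 the call ended for 3, 5 and 3 genes, at adjusted p of up to 0.153, 0.318 and 0.202. Without KO-labelled library 1, 2 or 3 it ended for 2, 4 and 4, at up to 0.0660, 0.0544 and 0.0668. Where a call ended, the largest shift of a log2 fold change was that of Chil3, from -4.94 to -4.68 without KO-labelled library 2.

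Prolactin and growth hormone transcripts together took 34.7% to 54.8% of the pituitary counts. The list of anterior pituitary hormones did not pass (camera adjusted p = 0.559), with Gh at 107210 ± 18021 and 158170 ± 40157 CPM and the shared subunit Cga at 3141 ± 92.5 and 2182 ± 302 CPM, neither past FDR 0.05. Of 40 lists 4 passed. All 4 kept their call without any 1 library, while the number of lists was 8 without wild-type library 3 or KO-labelled library 1 and 7 without KO-labelled library 2. All 14 endothelial genes had positive fold changes and 4 passed adjusted over the list alone (camera adjusted p = 1.69e-08, and adjusted p = 0.774 with an estimated correlation). Of 22 S phase genes 21 had negative fold changes and 0 passed adjusted over the list alone (camera adjusted p = 4.59e-06, and adjusted p = 0.913 with an estimated correlation). Of 9 genes of the intermediate and posterior lobes 8 had negative fold changes and 3 passed adjusted over the list alone (camera adjusted p = 0.000646, and adjusted p = 0.774 with an estimated correlation), with Col25a1 at 44.7 ± 6.04 and 23.8 ± 4.53 CPM. Of 6 neutrophil genes 5 had negative fold changes and 4 passed adjusted over the list alone (camera adjusted p = 0.00058, and adjusted p = 0.913 with an estimated correlation), with S100a9 at 15.1 ± 12.5 and 0.523 ± 0.126 CPM. Without wild-type library 3, S100a9 and Ngp passed over all genes at adjusted p = 2.35e-05 and 0.000243. The gonadotrope, receptor and transcription factor lists did not pass, at camera adjusted p of 0.529, 0.211 and 0.741. Adjusted over the list alone, 4 of 13 gonadotrope genes passed higher and 2 lower. For transcription factors these were 2 and 1 of 15, and 0 of 14 receptor genes passed. Dlk1 measured 1304 ± 246 and 1980 ± 54.8 CPM, Trhr 13.0 ± 2.61 and 8.68 ± 1.95 CPM, and Gata2 19.1 ± 2.61 and 30.3 ± 4.38 CPM, none of them past FDR 0.05. Cga passed without KO-labelled library 1 (adjusted p = 0.0360).

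In the ovary, 0 of 14460 genes passed by edgeR. An unadjusted p under 0.05 was found for 1110 genes where 723 would be given by chance, DESeq2 called 48 and limma-voom 0. In 1 edgeR fit over all 24 libraries, which shares the estimate of spread between tissues, 34 ovarian genes passed, 11 higher and 23 lower. The smallest p belonged to Mgat4c, a glycosyltransferase-like gene, at 56.4 ± 16.7 CPM (SD, n = 3) in wild type and 1.69 ± 0.862 CPM in KO-labelled libraries (edgeR adjusted p = 0.0875, and 0.0281 with GC and length trends removed). Klhl31 followed at 32.9 ± 2.21 and 9.62 ± 2.15 CPM, the pseudokinase gene Trib2 at 380 ± 38.3 and 135 ± 37.3 CPM, Ptprt at 6.33 ± 1.36 and 1.69 ± 0.0924 CPM, and 6330419J24Rik at 23.6 ± 8.34 and 7.25 ± 1.21 CPM, none past FDR 0.05. Without KO-labelled library 2 there were 2 calls, Mgat4c and Klhl31, each at adjusted p = 0.0391. In simulated ovary counts 74.2% of 4-fold and 4.48% of 2-fold changes were recovered. Those rates hold for 200 changed genes of at least 1 CPM, drawn independently and with no library that stands apart. With fewer real changes the adjusted threshold is stricter, so the rates are not those of the real ovary libraries.

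Of 39 lists in the ovary 13 passed by camera, 8 ranked higher and 5 lower, and none passed with an estimated correlation, where adjusted p ran from 0.617 up to 0.715. KO-labelled library 2 stood apart in this tissue. The 45S ribosomal RNA gene Rn45s took 3.87% of its counts and at most 0.168% in the other 5. This library lay at 97.2 on the first principal component (53.5% of the variance) and the others at -39.4 to -6.94. Across genes the rank correlation of its deviations with length was -0.590, where theirs were 0.175 to 0.366. The call of 11 of the 13 lists ended without 1 library or another, and the interferon and granulosa lists kept theirs. Without KO-labelled library 1, 2 or 3 the call ended for 6, 4 and 7 lists, at adjusted p of up to 0.315, 0.720 and 0.980, and without wild-type library 2 or 3 for 2 and 3, at up to 0.149 and 0.195. The number of lists was 8 without KO-labelled library 3. Granulosa genes of growing follicles ranked lower, 17 of 20 with negative fold changes and 0 past the threshold adjusted over the list alone (camera adjusted p = 0.000353, and adjusted p = 0.617 with an estimated correlation), with the FSH receptor gene Fshr at 38.4 ± 11.7 and 17.5 ± 3.89 CPM. Of 22 S phase genes 20 had negative fold changes and 0 passed adjusted over the list alone (camera adjusted p = 0.00032, and adjusted p = 0.617 with an estimated correlation). Of 24 interferon-stimulated genes 22 had positive fold changes and 0 passed adjusted over the list alone (camera adjusted p = 0.00032, and adjusted p = 0.617 with an estimated correlation), with Irf7 at 12.9 ± 2.78 and 22.7 ± 5.78 CPM. Of 16 macrophage genes 6 passed adjusted over the list alone, all higher, C1qa measuring 67.9 ± 8.83 and 121 ± 35.7 CPM (camera adjusted p = 0.000583, and adjusted p = 0.617 with an estimated correlation). The clock list ranked higher with 1 of 15 genes past the threshold adjusted over the list alone (camera adjusted p = 0.00373, and adjusted p = 0.617 with an estimated correlation). Its genes Per3 and Dbp measured 20.9 ± 1.29 and 42.4 ± 9.06 CPM, and 60.4 ± 29.2 and 158 ± 26.7 CPM. The other lists ranked higher were endothelium (1 gene past the threshold adjusted over the list alone), and, with 0 such genes each, ribosomal proteins, cholesterol synthesis, smooth muscle and lymphocytes. Those ranked lower were oocyte, heat shock and implantation genes, also with 0 each. With an estimated correlation these were at adjusted p = 0.715 for ribosomal, cholesterol and oocyte genes and at adjusted p = 0.617 for the others. With GC and length trends removed the implantation and lymphocyte calls ended, at adjusted p = 0.0564 and 0.0684. The ribosomal list turned to rank lower without KO-labelled library 2 (adjusted p = 0.110). Lists of steroidogenesis, corpus luteum, theca, ovulation and oviduct did not pass, at camera adjusted p of 0.231, 0.166, 0.306, 0.0604 and 0.644. Akr1c18, the enzyme that inactivates progesterone, measured 135 ± 93.9 and 27.2 ± 8.39 CPM and did not pass.

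In the hypothalamus, 0 of 14788 genes passed by edgeR. An unadjusted p under 0.05 was found for 999 genes where 739 would be given by chance, DESeq2 called 7 and limma-voom 0. Among the smallest p values were those of Rps4l with a log2 fold change of -2.36 (SE 0.41), Sh3bgrl2 at 30.3 ± 1.39 and 10.2 ± 4.15 CPM (SD, n = 3), Malat1 at 108 ± 7.58 and 43.6 ± 11.2 CPM, and Zfp951 at 3.20 ± 0.573 and 0.293 ± 0.327 CPM, each at edgeR adjusted p = 0.588. Rps4l was at adjusted p = 0.00435 with GC and length trends removed. Of 40 lists 5 passed, 3 without wild-type library 2, 9 without wild-type library 3 and 11 without KO-labelled library 2. KO-labelled library 2 held 1.21% Rn45s and the others at most 0.287%, and across genes the rank correlation of deviations with GC content was -0.633, -0.242 and -0.239 in wild type and 0.0633, 0.722 and -0.225 in KO-labelled libraries. Of 30 neuropeptide genes 26 had positive fold changes and 0 passed adjusted over the list alone (camera adjusted p = 9.54e-05, adjusted p = 0.940 with an estimated correlation, and 0.283 with GC and length trends removed). They included the feeding peptide gene Agrp at 1.99 ± 0.633 and 5.67 ± 1.68 CPM and the oxytocin gene Oxt at 114 ± 22.7 and 343 ± 283 CPM. All 24 ribosomal protein genes had positive fold changes and 0 passed adjusted over the list alone (camera adjusted p = 1.67e-06, and adjusted p = 0.940 with an estimated correlation). Extracellular matrix genes ranked higher, with 4 of 18 past the threshold adjusted over the list alone and Col1a2 at 11.3 ± 2.84 and 26.3 ± 14.3 CPM (camera adjusted p = 0.000662, and adjusted p = 0.940 with an estimated correlation). Sex steroid and prolactin receptors ranked lower, with Prlr at 55.8 ± 25.2 and 29.1 ± 11.4 CPM, and skeletal muscle genes higher, with 0 past the threshold adjusted over the list alone in either. Those receptor and muscle lists were at camera adjusted p of 0.006 and 0.0314, at adjusted p = 0.940 with an estimated correlation, and at 0.325 and 0.169 with GC and length trends removed. Without wild-type library 2 they were at 0.0527 and 0.0549, and the muscle list was at 0.0794 without wild-type library 3, 0.0938 without KO-labelled library 1 and 0.0631 without KO-labelled library 3. The lists of GnRH and prolactin control, GABA and glutamate neurons, oligodendrocytes, astrocytes, choroid plexus and other forebrain did not pass, at camera adjusted p of 0.968, 0.166, 0.968, 0.941, 0.968 and 0.753.

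The genotype effect differed between tissues for 9 of 16971 genes by the interaction test. The genes were Mgat4c, Slc5a5, S100a8, Acot7, Trib2, Sox2ot, Arvcf, Chst10 and Atg9b. In the 24-library fit Mgat4c had a log2 fold change of -5.01 in the ovary and 0.39 in the uterus, and Slc5a5 one of -3.26 in the uterus and 2.22 in the ovary. S100a8, a neutrophil protein gene, was at 2.33 in the uterus and -5.76 in the pituitary. Before TMM scaling its pituitary values were 19.1, 50.3 and 2.01 CPM in wild-type and 0.377, 0.0998 and 0.545 CPM in KO-labelled libraries. The size of its change there thus rests on few reads and on widely spread wild-type values. The number of genes passing the interaction test was 4 with RLE scaling and 163 with DESeq2. On simulated counts 32 of 258 calls of this test were false. In the real data the number was 2 without wild-type number 1 or 2 and 4 without wild-type number 3. It was 3 without KO-labelled number 1 and 21 without KO-labelled number 2, each number left out in all 4 tissues. Of 138 contrasts of 23 lists between pairs of tissues, 50 passed by camera and none with an estimated correlation, where the smallest adjusted p was 0.0548. These contrasts used list genes that passed the filter over all 24 libraries, also where a gene did not pass it in a tissue compared. The S phase list ranked higher in the uterus than in the pituitary (camera adjusted p = 1.46e-22, and adjusted p = 0.0633 with an estimated correlation).

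Rps4l was the 1 gene called the same way in more than 1 tissue. It was lower in uterus and pituitary, where 0.00519 shared genes would be given by independent lists of 23 and 3 genes (one-sided exact hypergeometric p = 0.00518, adjusted p = 0.0622). Its fold change differed between uterus and hypothalamus by 1.95 on the log2 scale (edgeR adjusted p = 0.0447 over 6 pairs of tissues). DESeq2 called 10 genes in more than 1 tissue. Chosen after the values were seen, genes whose 3 KO-labelled values lay on 1 side of the wild-type values in all 4 tissues were counted. Of 12522 genes tested in every tissue, 11 were lower and 4 higher, where chance in independent tissues gives 0.0783 each way. Over all genes tested, groups did not overlap for 17.8% in the ovary, 19.5% in the uterus, 19.6% in the pituitary and 10.9% in the hypothalamus. Chance gives 10% in each. The lower genes were Rps4l, Zfp951, Sh3bgrl2, Csf2ra, Pcdhga11, Cstf2t, Fam65b, Pramef8, Rdx, 2610005L07Rik and 6820431F20Rik, and the higher genes Dgkz, Il34, Psmb9 and Ptger1. With GC and length trends removed 7 of the lower and 0 of the higher genes kept the separation.

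**Figure D3:**
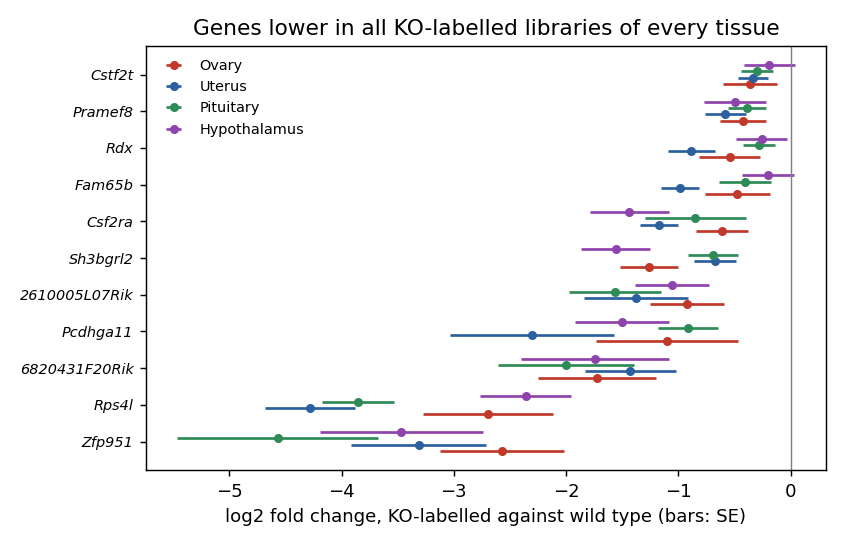
Log2 fold change (x axis, bars are SE, 3 against 3 libraries) in each tissue of the 11 genes whose KO-labelled libraries all lay below the wild-type libraries in every tissue. Rps4l ranges from -4.28 in the uterus to -2.36 in the hypothalamus.

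The authors' deposited table listed 53, 532, 39 and 7 genes at an adjusted p under 0.05 in ovary, uterus, pituitary and hypothalamus. It included all 52 uterine and 5 of the 6 pituitary edgeR calls. For Chil3 the table gave no adjusted p. Its fold change for Mgat4c in the ovary was -3.66, with an adjusted p of 1.92e-28.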

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

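Tests chosen after the result was seen were the share of epithelium in the uterus and the count and place of genes lower in all tissues, and the fits with GC and length trends removed were added after seeing the data.

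Effects that differed between tissues by the interaction test were those of Mgat4c (adjusted p = 0.000179), Slc5a5 (0.000685), S100a8 and Acot7 (0.0235 each), Trib2 (0.0349), and Sox2ot, Arvcf, Chst10 and Atg9b (0.0475 each). The real grouping gave 9 genes and the highest of the other regroupings within tissues 3. It was 1 of 40 with as many, so chance can be excluded at 0.05 for that count if the tissues are independent, which the labels do not state.

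For each list whose effect differed between tissues by camera at the preset correlation, the pair of tissues with its smallest p is given, and none passed with an estimated correlation. Pituitary differed from uterus in S phase (adjusted p = 1.46e-22), neutrophil (4.33e-11) and oestrogen-induced genes (2.9e-05). Hypothalamus differed from pituitary in extracellular matrix (7.002e-08), endothelium (4.64e-05), skeletal muscle (0.000645), ribosomal proteins (0.00119), smooth muscle (0.00168) and lobe genes (0.033). Pituitary differed from ovary in interferon-stimulated (7.31e-06), corpus luteum (5.02e-05) and implantation genes (0.0307). Uterus differed from ovary in heat shock (1.32e-05), oocyte (2.63e-05), macrophage (0.00829) and adipose genes (0.011). Hypothalamus differed from ovary in granulosa (0.00119) and cholesterol genes (0.00435). The oocyte contrast used 25 genes, and 6 were tested in the uterus alone. The granulosa contrast used 20 genes against 14 in the hypothalamus, and the corpus luteum contrast 17 against 12 in the pituitary. The oestrogen-induced contrast used 20 genes against 10 in the pituitary, and the neutrophil contrast 10 against 6 there. The smooth muscle contrast used 12 against 8 in the pituitary, the implantation contrast 23 against 16 in the ovary, and the adipose contrast 13 against 7 in the uterus. The skeletal muscle contrast used 10 genes, of which fewer than 5 were tested in the pituitary. For these lists a different effect cannot be told apart from low counts in the tissue where fewer of the genes were tested.

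In the uterus the S phase and oestrogen-induced lists ranked higher and the progesterone-induced list lower by camera at the preset correlation, while none passed with an estimated correlation (adjusted p = 0.328, 0.0615 and 0.328). Library trends over GC content and length are argued against as the whole cause, since the largest adjusted p of the 3 lists was 5.26e-07 with the trends removed. A single library is argued against too, since all 6 of the leave-one-out fits kept the 3 lists past the threshold. More epithelium is argued against by the epithelium list, whose median log2 fold change was 0.25 (SD 0.64 over its genes) where that of the oestrogen-induced list was 1.64. Genotype and differences between single uteri stay open, since 10 splits are too few for a share under 0.05. All 3 lists passed in this combination or its mirror in 3 of the 10 splits, the real one included. The S phase, oestrogen-induced and progesterone-induced lists were called in 5, 6 and 5 of the 10 splits, and each had its smallest p in the real one.

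In the ovary 13 lists were called at the preset correlation and 0 with an estimated correlation (adjusted p = 0.617 to 0.715). No gene was called by edgeR in the 6 libraries, where 1110 genes had an unadjusted p under 0.05, while edgeR over 24 libraries called 34, DESeq2 48 and limma-voom 0. With the trends removed 84.6% of these lists stayed called in their direction, which argues against GC content and length as the whole cause. Without KO-labelled library 2, the library with 3.87% Rn45s, 69.2% stayed, and the calls that ended were 4, against 6 and 7 without KO-labelled library 1 or 3, while the ribosomal list lost its call and turned without this library alone (adjusted p = 0.110). Over the 10 splits of the 6 libraries, the real one had the smallest p for 2 of the 13 lists. As small a p or smaller was found in 10 splits for ribosomal and 7 for oocyte genes, the real split included. For cholesterol and for implantation genes it was found in 6. Genotype, the biological explanation that the design names, and differences between single ovaries stay open, since 10 splits are too few for a share under 0.05.

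For the counts of calls per tissue 10 splits of the 6 libraries are too few for a share under 0.05. The real and highest other counts of genes by edgeR were 52 and 0 in the uterus and 6 and 1 in the pituitary. They were 0 and 0 in the ovary and in the hypothalamus, where 1110 and 999 genes had an unadjusted p under 0.05, DESeq2 called 48 and 7 and limma-voom 0. Those of lists were 13 and 13 in the ovary, 8 and 17 in the uterus, 4 and 9 in the pituitary, and 5 and 11 in the hypothalamus. In each tissue another split thus called as many lists as the real one or more. For genes called in more than 1 tissue the real count was 1 and the highest other 1, in 3 of 100 drawn combinations of splits. Of these combinations 4 had calls in more than 1 tissue at all, so that this count restates those per tissue and decides nothing, and the overlap test gave an adjusted p of 0.0622.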

How the results depend on the processing

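Fits with GC and length trends removed, with Prl and Gh left out and with both ovarian libraries numbered 2 left out were chosen after seeing the data, and unless stated the cause of a change was not tested. DESeq2 called 48 genes in the ovary, 542 in the uterus, 48 in the pituitary and 7 in the hypothalamus, 163 in the interaction and 10 in more than 1 tissue. With no filter, where more genes were tested, 1, 108 and 16 passed in ovary, uterus and pituitary. Limma-voom called 1 in the pituitary, the fit over 24 libraries 34 in the ovary, and RLE scaling gave 4 in the interaction. With trends removed 1, 99 and 1 genes passed in ovary, uterus and hypothalamus, and 7 lists in the pituitary. With an estimated correlation 0 lists passed in each tissue, and with fry 0, 1, 0 and 0. Leaving out 1 library gave 0 to 2 genes in the ovary, 0 to 171 in the uterus, 1 to 10 in the pituitary and 2 to 21 in the interaction, and 8 to 15, 7 to 11, 5 to 8 and 3 to 11 lists in ovary, uterus, pituitary and hypothalamus. The uterine count fell without any wild-type library and rose without any KO-labelled one.

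Directions were followed for the named genes alone, and among these they turned only for genes not called. In the ovary the ribosomal list turned without KO replicate 2, and its adjusted p ran from 5.15e-07 to 0.110 over the fits without 1 library. With both libraries numbered 2 left out it (0.0113) and the cholesterol list (0.99992) turned. Without 1 library the log2 fold change ran from -0.38 to 0.0491 for uterine Ptprf (turned without WT 1 and KO 1) and from -0.16 to 0.16 for uterine St3gal3 (WT 3 and KO 1). It ran from -0.18 to 0.0942 for pituitary Kdm4a (turned without WT 2, KO 2 and KO 3) and from -0.17 to 0.31 for hypothalamic Ptprf (WT 3 and KO 2). With trends removed St3gal3 turned to -0.0668 in the uterus and -0.0471 in the pituitary, and in the hypothalamus Gria2 turned to 0.23 and Foxj1 to -0.19.

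The label numbers were not found to pair the libraries. Deviations of same-numbered libraries correlated at -0.26, -0.16 and -0.07 across genes in the ovary, -0.15, -0.10 and -0.03 in the uterus, 0.16, 0.06 and 0.03 in the pituitary and 0.04, 0.25 and -0.30 in the hypothalamus. Not every library correlated best with its own number. With the replicate block 0, 38, 33 and 0 genes passed in ovary, uterus, pituitary and hypothalamus. Of the 38 uterine genes 26 were among the 52 called without the block, and the 33 pituitary genes held all 6. With it passed 15, 10, 6 and 5 lists, 2 genes in the interaction and 1 gene in more than 1 tissue. Depth limits low genes, since 1 count was worth up to 0.0757 CPM.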

Other observations

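The tests of the count and of the place of genes lower in all tissues were chosen after the result was seen, and so were the fits with GC and length trends removed. Transcripts of pituitary hormones were counted in the other tissues. Prl measured 4.82, 27.6 and 165 CPM in wild-type and 15.1, 267 and 91.3 CPM in KO-labelled uteri, and Gh 1.95, 11.4 and 73.8 and 6.24, 138 and 41.9 CPM in the same libraries, before TMM scaling. In the ovary, Adipoq, a fat cell hormone, ranged from 0.129 to 170 CPM in wild-type libraries, and Star, which moves cholesterol into mitochondria for steroid synthesis, from 826 to 9764 CPM over all 6. Rn45s took 1.21% of the counts of hypothalamic KO-labelled library 2 and at most 0.287% in the other 5.

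Of 11 genes lower in the KO-labelled libraries of all 4 tissues, 9.09% lay on the chromosome of Kdm4a, which argues against DNA beside the targeted gene as the cause for the others. The real grouping gave 11 genes and the highest of the other drawn combinations of splits 3, 1 of 100 with as many. Since the count was itself chosen from these data, that share does not exclude chance. It also takes the tissues as independent, which the labels do not state. Across genes, fold changes of pairs of tissues correlated at 0.0374 (uterus and pituitary) to 0.418 (pituitary and hypothalamus). With GC and length trends removed 63.6% kept the separation, among them Rps4l, Zfp951, Sh3bgrl2, Csf2ra and Pcdhga11, so that such trends may account for part of the set. Segregating stretches of another strain's DNA remain a candidate explanation, but 1 pair of the genes lay within 5 Mb, where the 95th percentile of 1000 random sets was 1, and that pair was 2610005L07Rik and 6820431F20Rik, so the test could not decide.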
